A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

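Transcript levels were measured in 4 cultures of Saccharomyces cerevisiae, 2 wild type and 2 dis3-E729K, on 1-colour Affymetrix arrays. Per the labels' protocols, strains grew overnight at 30 °C in drop-out medium, were diluted and collected in mid-log phase by optical density, and total RNA was amplified and labelled with biotin. Density at collection is not given per culture in the sources used here. Groups and replicate numbers came from the sample titles, which call the samples biological replicates.

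The deposited values are log2 intensities, 1 per probe set and array; per the submitters' processing notes, Affymetrix Expression Console, RMA and Transcriptome Analysis Console were used, with no versions given. RMA subtracts background, quantile-normalizes the arrays together and summarises the probes of a set on the log2 scale. Quantile normalization gives all arrays the same distribution, so a global rise or fall of mRNA per cell cannot be seen. Signal of bright probe sets may be compressed, which was not measured. The table held 10928 probe sets with 0 missing values. Through the platform's annotation and the Entrez identifiers of the RefSeq genes of assembly R64, 5498 probe sets were tied to exactly 1 S. cerevisiae gene, 1746 to genes of another species and 1 to several genes; 213 were controls and 3470 had no gene here. Symbols were updated for 12 probe sets. No genome build is named in the sources used here, so no coordinates are given. Where a gene had more than 1 probe set (47 genes), the one with the highest mean over all 4 arrays was kept, without regard to group, which left 5449 genes. Probe sets whose identifiers mark cross-hybridisation (128) were kept and are named as uncertain.

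Mutant and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, no filter on dim genes), with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05 on the adjusted p. Changes are log2 differences, mutant minus wild type, with the moderated SE. The fit had 2 residual and 2.18 prior degrees of freedom. Because p-values rest on 2 cultures per group, they measure the spread between these cultures. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 32 lists with at least 3 measured members; camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 of 10 calls held, with 1 list at an unadjusted p under 0.05; fry called 1 of the 10, the Hsf1 chaperones, and 1 further list. An older gene name shared by several genes was read as the gene the list already held. A background level was set as the 95th percentile of probe sets of the other species, 4.06 on the mean of the arrays. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

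Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose mutant arrays both lay on the same side of both wild-type arrays. Further named were DIS3, its protein-coding neighbours and the marker genes URA3, HIS3, LEU2 and MET17, up to 4 members of each list with the largest absolute moderated statistic, and the brightest member of each list for cells the cultures should lack. Genes behind a count of 5 or fewer that the rule did not reach (PRE3, MAG1, ISU1, FTR1, MRPL28, MRPL1, IME4 and SPO11), and the STE2, MFA2, HMLALPHA1, HMRA1, HXT1, HXT2, ICL1, MLS1, CAT8, HSP12, HSP26, HXT5, ZPS1 and YOR387C genes, were named after their values were seen.

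The procedure was tested on simulated data for this comparison, 20 data sets of 5449 genes with the real means and the fitted spread. It called 0.2% of genes changed by 0.5 log2 units, 13.6% at 1, 78.6% at 2 and 93.5% at 3, and 0.106% of unchanged genes. Few simulated genes were changed, where the real data had 986 higher and 1231 lower at an unadjusted p under 0.05 in limma's test. Simulated errors were also independent between genes, so these rates need not hold for the real comparison. Camera called 100 of 100 lists of 30 genes shifted by 0.5 and 0 of 500 unshifted lists, whose simulated genes were independent.

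The alternatives were the replicate number as a block, an intensity trend or robust fit in eBayes, no variance moderation, quantile normalization or median centring over the tested genes, dim genes left out, all probe sets except controls, the average of a gene's probe sets, cross-hybridising probe sets left out, other thresholds, and each array left out in turn. Blocked and within-pair values are given because mating type genes split the arrays by replicate number.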

Results

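The series measured transcript levels in budding yeast that carry dis3-E729K, a missense allele of DIS3, and in wild-type cells. DIS3 encodes the catalytic ribonuclease of the RNA exosome, the complex that degrades and trims RNA from the 3' end. Total RNA from 4 log-phase cultures grown at 30 °C was hybridised to 4 one-colour Affymetrix arrays, 2 of wild type and 2 of dis3-E729K. Per the labels, all cultures had the BY4741 background, a standard laboratory strain, and both genotypes carried a URA3 marker beside DIS3. The labels call the samples biological replicates. The values are RMA log2 intensities, whose quartiles were near identical between arrays: the lower quartile of the 5449 genes tested lay between 9.22 and 9.27 and the upper between 11.30 and 11.32. Probe sets for a second yeast species on the same array had medians of 2.89 to 2.93, and 98.6% to 98.8% of the genes tested lay above their 95th percentile on each array. LEU2, deleted in BY4741, lay above that percentile too, so this share may overstate the genes with true signal. The number of arrays, 4, limits the precision of every value below.

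The comparison of dis3-E729K with wild type asks which transcripts change when the exosome's ribonuclease is altered. Genes of the environmental stress response were higher in the mutant, with a median log2 change of 1.94 over 44 genes, as were chaperone and proteasome genes, with medians of 0.42 and 0.44. Genes of the G1/S transition, with a median of -1.01 over 28 genes, and of ribosome biogenesis, with a median of -0.76 over 89, were lower. These shifts passed limma's camera test with a preset correlation, and each had an adjusted p = 0.816 with an estimated correlation. Singly, 21 of the 44 stress genes, 10 of 25 chaperone genes and 5 of 34 proteasome genes rose, and 20 of the 28 G1/S genes and 15 of the 89 ribosome biogenesis genes fell. In limma's test 420 genes rose and 444 fell at a Benjamini-Hochberg adjusted p under 0.05, of 5449 tested. Of these, 283 rose and 240 fell by at least 1 log2 unit. At an unadjusted p under 0.05, 986 genes were higher and 1231 lower. The smallest adjusted p was 0.0335. Both mutant arrays lay on the same side of both wild-type arrays for 4040 genes, 74.1%, where chance gives 33.3%. Across genes, the wild-type arrays correlated at r = 0.965 and the mutant arrays at r = 0.962, and pairs from different genotypes at 0.859 to 0.943; genes are not independent replicates. The counts depended on single arrays. Without wild type replicate 1, 164 genes rose and 85 fell; without wild type replicate 2, 9 rose and 2 fell; without dis3-E729K replicate 2, 0 genes passed limma's test in either direction, with 694 higher and 868 lower at an unadjusted p under 0.05. With the replicate number as a block, 199 genes rose and 144 fell. Beside these changes, all 17 ribosomal RNA control probe sets were higher on both mutant arrays than on both wild-type arrays, with a median difference of 0.42. The signal of 5' relative to 3' probe sets was higher on both mutant arrays for 6 of 8 yeast control genes, by a median of 0.20 over the 8, and for 0 of 4 transcripts spiked in from Bacillus.

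The largest rise was that of ADY2 (YCR010C), an acetate transporter, from 6.08 ± 0.21 to 11.20 ± 1.43 (log2, SD, n = 2 each), a 35.0-fold difference with a log2 change of 5.13 ± 0.72 (SE). JEN1, a carrier of lactate and pyruvate, rose by 3.93 ± 0.45, SFC1, a mitochondrial carrier of succinate and fumarate, by 4.15 ± 0.59, and MPC3, a subunit of the mitochondrial pyruvate carrier, by 3.95 ± 0.39. RGI1, which is induced under respiratory growth, rose from 9.64 ± 0.14 to 13.79 ± 0.25 (n = 2), a 17.8-fold difference. GSY1, a glycogen synthase, rose by 3.70 ± 0.69. The other 6 genes named for their rise were YNL194C, YGR067C, ISF1, AIM17, YKR075C and TMA10, with log2 changes from 3.63 for TMA10 to 4.85 for YNL194C. Adjusted p values of the 12 lay between 0.0335 for RGI1 and 0.0454 for YNL194C, whose adjusted p was 0.0576 with the replicate block. Expression was higher in dis3-E729K replicate 2 than in replicate 1 for each of the 12, as for ADY2 at 12.22 and 10.19.

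**Figure D1:**
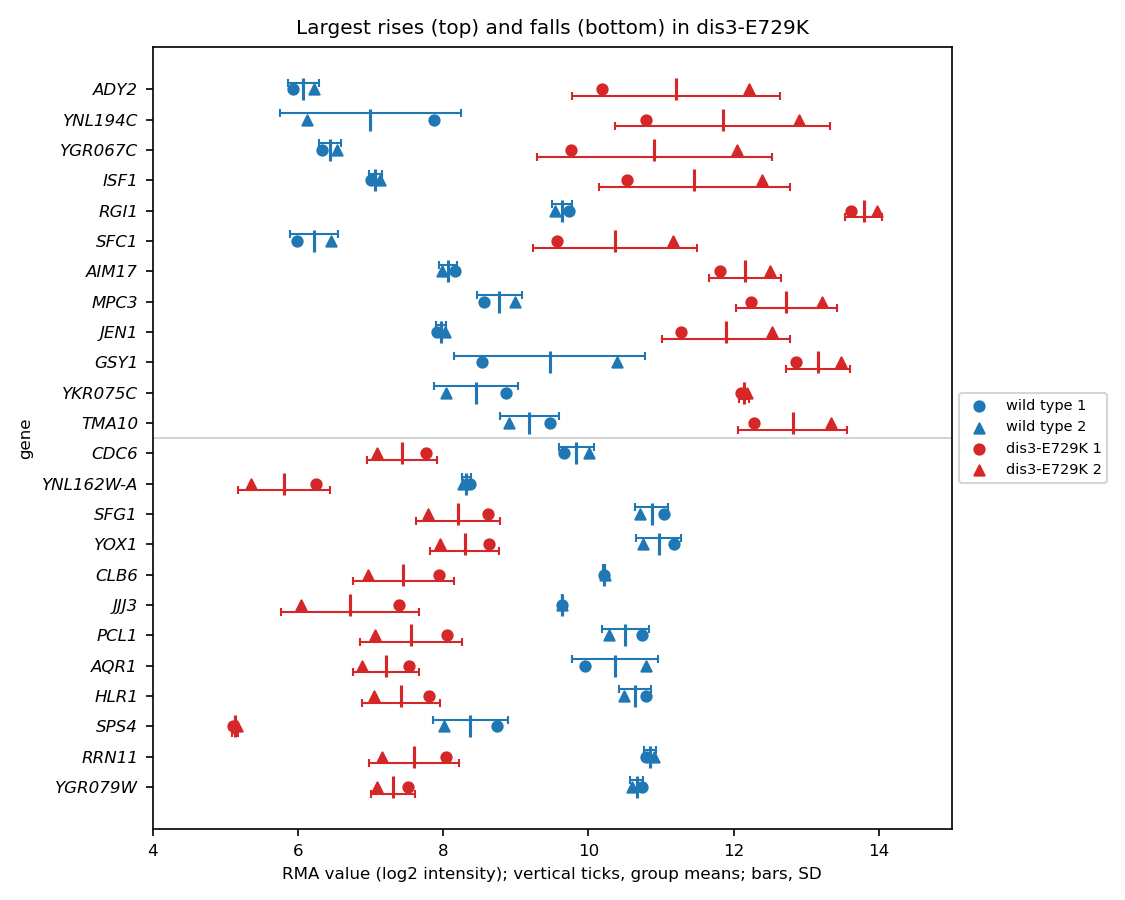
RMA values (log2 intensity, x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis), 1 point per array, with ticks at the group means and bars of 1 SD (n = 2). For every gene drawn, both mutant arrays lie on the same side of both wild-type arrays; ADY2 reads 5.93 and 6.22 in wild type and 10.19 and 12.22 in the mutant.

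The largest fall was that of YGR079W, from 10.66 ± 0.10 to 7.31 ± 0.30 (n = 2), 10.3-fold, with a log2 change of -3.36 ± 0.19 (SE). RRN11, a subunit of the core factor of RNA polymerase I, fell by 3.25 ± 0.33. The log2 change was -2.95 ± 0.39 for PCL1, a G1 cyclin, -2.76 ± 0.36 for CLB6, an S-phase cyclin, and -2.40 ± 0.29 for CDC6, which loads the replicative helicase at origins. YOX1, a repressor of genes expressed at the M/G1 boundary, fell by 2.67 ± 0.30. The remaining 6 were SPS4, HLR1, AQR1, JJJ3, SFG1 and YNL162W-A, with changes from -3.24 for SPS4 to -2.52 for YNL162W-A. Adjusted p values of the 12 lay between 0.0335 for YGR079W and 0.0395 for JJJ3.

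Genes induced in the environmental stress response were higher in the mutant: 21 of 44 measured members rose, 0 fell, and 27 rose adjusted over the list alone. With the replicate block 18 rose. The median change over the list was 1.94 log2 units, with 1.23 between the replicate 1 arrays and 2.87 between the replicate 2 arrays. GLC3, the glycogen branching enzyme, rose by 3.50 ± 0.31 (SE), TPS2, a phosphatase of trehalose synthesis, by 2.46 ± 0.22, PNC1, the nicotinamidase, by 2.12 ± 0.20, and HSP104, a protein disaggregase, by 1.43 ± 0.12. Other members did not rise: HSP12 and HSP26 differed by -0.03 ± 1.19 and -0.10 ± 1.18 and did not pass. Both were lower in the mutant in the replicate 1 pair and higher in the replicate 2 pair. In limma's camera test with a preset correlation the list was higher at an adjusted p of 6.71e-12, and at an adjusted p = 0.816 with an estimated correlation. Of the 25 chaperone genes driven by the heat shock factor Hsf1, 10 rose and 0 fell, and 11 rose adjusted over the list alone; 6 rose with the replicate block. Their median change was 0.42, 0.47 and 0.46 within the pairs (camera adjusted p = 1.91e-04; adjusted p = 0.816 with an estimated correlation). HSP42, a small heat shock protein, rose by 2.45 ± 0.26, BTN2 by 1.92 ± 0.19 and CUR1 by 1.68 ± 0.13; the last 2 sort misfolded proteins. The stress and chaperone lists share 5 genes, 3 of which rose. The proteasome list rose as a set, with 34 of 34 subunits above zero, a median of 0.44 and medians of 0.38 and 0.50 within the pairs (camera adjusted p = 1.95e-09; adjusted p = 0.816 with an estimated correlation). Single subunits passed for RPN11 (0.84 ± 0.12), PRE8, RPN12, PRE3 and RPT3, and 13 adjusted over the list alone. With the replicate block 0 of 34 subunits passed limma's test, with 13 higher at an unadjusted p under 0.05.

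Genes of the G1/S transition were lower: 20 of 28 fell, 0 rose, and 24 fell adjusted over the list alone. With the replicate block 13 fell. The median change was -1.01, with -1.18 and -1.01 within the pairs (camera adjusted p = 9.92e-10; adjusted p = 0.816 with an estimated correlation). MCD1 and SMC3, subunits of cohesin, fell, with log2 changes of -2.07 ± 0.18 and -1.51 ± 0.13 (SE), as did CDC45, a component of the replicative helicase, at -1.56 ± 0.13 and CLB5, an S-phase cyclin, at -1.44 ± 0.13. Of 30 genes expressed at G2/M and M/G1, 10 fell and 0 rose. Adjusted over the list alone, 14 fell and 1 rose, and with the replicate block 2 fell, CLB1 and CDC5. Their median was -0.49, with -0.26 and -0.61 within the pairs (camera adjusted p = 9.52e-03; adjusted p = 0.816 with an estimated correlation). Among them were CLB1, a mitotic cyclin (-1.61 ± 0.13), CDC5, the polo kinase (-1.15 ± 0.13), ALK1 (-1.12 ± 0.15) and BUD4 (-1.05 ± 0.14). In the list for kinetochore, spindle and cohesion, 17 of 56 genes fell and 0 rose, and 25 fell and 1 rose adjusted over the list alone. The replicate block left 7 falls. Its median was -0.40, with -0.36 and -0.42 within the pairs (camera adjusted p = 9.77e-06; adjusted p = 0.816 with an estimated correlation). The log2 change was -2.36 ± 0.21 for BUB1, a spindle checkpoint kinase, and -1.19 ± 0.12 for DAD4, of the Dam1 complex. This list and the G1/S list share 3 genes, all of which fell.

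Genes for ribosome biogenesis were lower, with 0 of 89 above zero. Over all genes tested 15 fell, and 47 fell adjusted over the list alone; 6 fell with the replicate block. The median change was -0.76, with -0.44 between the replicate 1 arrays and -1.05 between the replicate 2 arrays (camera adjusted p = 1.47e-11; adjusted p = 0.816 with an estimated correlation). SSF1, which acts in large subunit assembly, fell from 10.34 ± 0.03 to 8.38 ± 0.21 (n = 2), and UTP18 and UTP9, of the small subunit processome, fell with log2 changes of -1.94 ± 0.31 and -1.53 ± 0.24 (SE). DBP8, an RNA helicase, fell by 1.70 ± 0.26. Of 128 cytosolic ribosomal protein genes, 3 fell in limma's test, RPL22B (-1.52 ± 0.26), RPS22B (-0.89 ± 0.18) and RPS14B (-0.63 ± 0.12). Adjusted over the list alone 0 passed, with 25 lower at an unadjusted p under 0.05, and RPL22B alone fell with the replicate block. The median over the list was -0.22, with -0.14 and -0.30 within the pairs (camera adjusted p = 1.18e-05; adjusted p = 0.816 with an estimated correlation), and -0.15 without dis3-E729K replicate 2. These genes are bright, and array signal may be compressed at such levels, which was not measured. The same limit would hold for other bright genes, such as RGI1 at 13.79 in the mutant. The ribosomal RNA control probe sets moved the other way, with medians of 0.45 and 0.39 within the pairs.

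Among the 22 genes of the exosome and its cofactors 3 fell and 0 rose, and 1 fell adjusted over the list alone. With the replicate block TRF5 and AIR1 fell and RRP4 did not pass (adjusted p = 0.0958). TRF5, a poly(A) polymerase of the TRAMP complex that marks RNA for the exosome, fell from 10.31 ± 0.10 to 8.03 ± 0.48 (n = 2), 4.86-fold. AIR1, an RNA-binding subunit of TRAMP, fell by 2.28 ± 0.45 (SE), and RRP4, an RNA-binding cap subunit, fell by 0.71 ± 0.14. AIR2, the paralogue of AIR1, did not pass, at 0.57 ± 0.13 and an adjusted p of 0.0532. The median of the list was -0.40, with -0.17 and -0.58 within the pairs (camera adjusted p = 9.88e-03; adjusted p = 0.816 with an estimated correlation), and -0.23 without dis3-E729K replicate 2. In the list for Nrd1-Nab3-Sen1 termination and its target genes, 1 of 12 rose: URA8, a CTP synthetase, by 1.25 ± 0.14. Adjusted over the list alone 4 rose and 1 fell. NRD1 (0.74 ± 0.16, adjusted p = 0.0515), ADE12 (0.71 ± 0.15, adjusted p = 0.0521) and NAB3 (0.55 ± 0.14, adjusted p = 0.0690) did not pass over all genes. The list was not called (camera adjusted p = 0.478), and its mean of 0.12 and median of -0.08 differ in sign. Of 21 genes for 5' to 3' decay and decapping, EDC2, an activator of decapping, rose by 1.55 ± 0.24, and 0 passed in limma's test adjusted over the list alone, with 4 higher and 3 lower at an unadjusted p under 0.05. That list was not called (median -0.16, camera adjusted p = 0.957). URA8 passed with the replicate block (adjusted p = 0.0450) and EDC2 did not (adjusted p = 0.0509). The list of small nuclear and nucleolar RNA genes had 0 measured members.

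**Figure D2:**
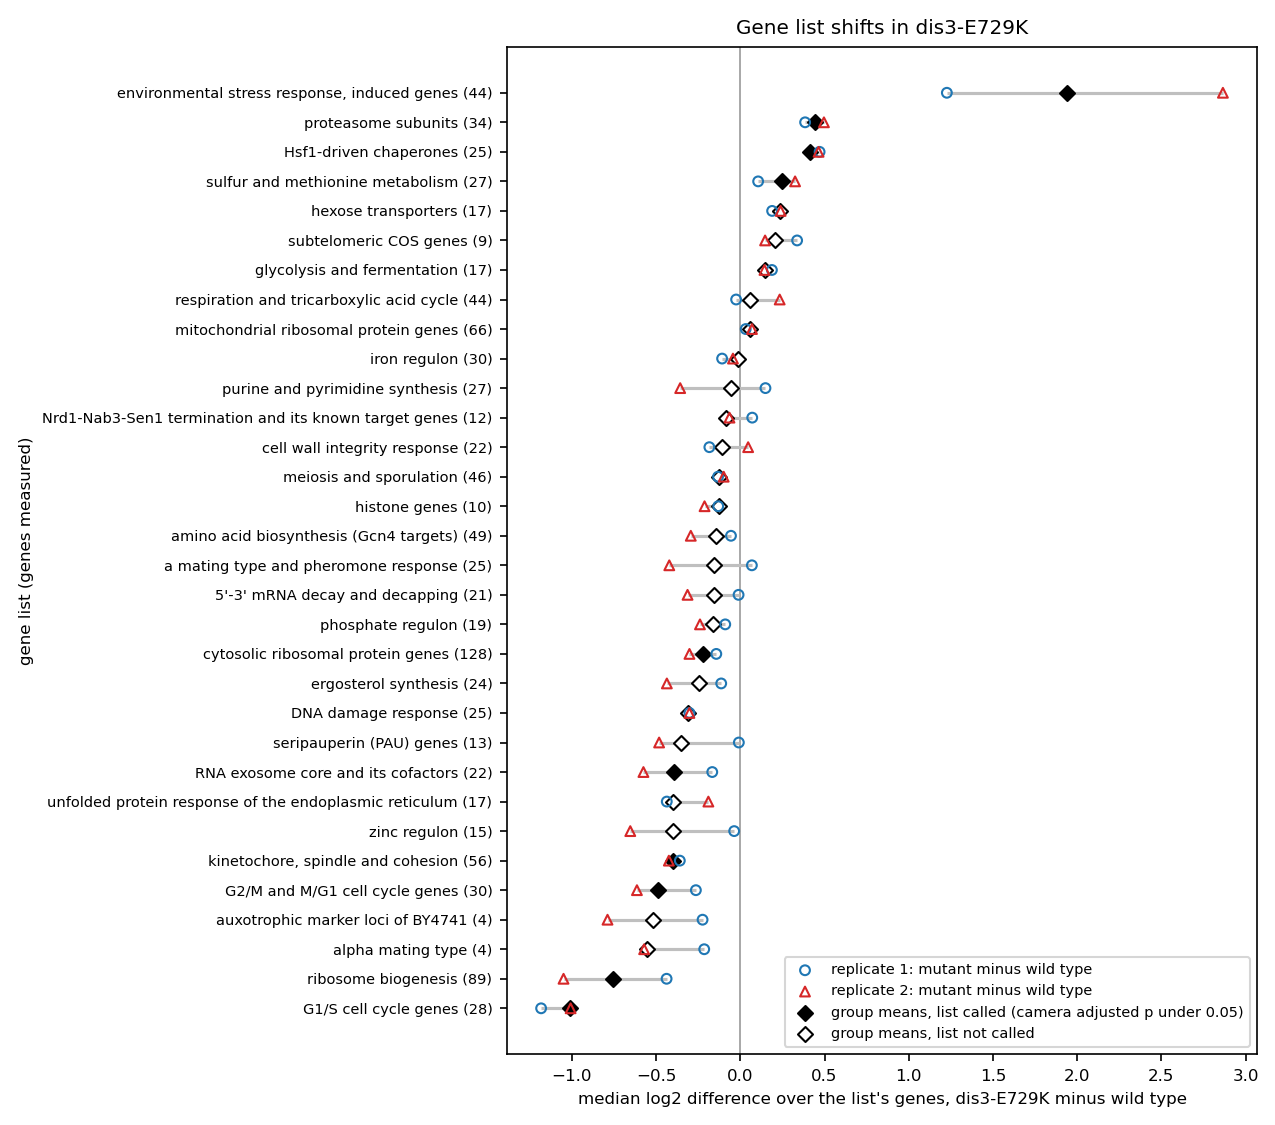
Median log2 difference between dis3-E729K and wild type (x axis) over the genes of each of 32 lists (y axis, genes measured in brackets), for the group means (diamonds, filled where camera's adjusted p was under 0.05) and within the replicate 1 pair (circles) and the replicate 2 pair (triangles). The stress list has a median of 1.94, and the lowest medians are those of the G1/S list at -1.01 and ribosome biogenesis at -0.76.

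The list for sulfur and methionine metabolism was called higher with a small median of 0.25, with 0.11 and 0.32 within the pairs (camera adjusted p = 0.0169; adjusted p = 0.816 with an estimated correlation). Of its 27 genes only SAM2, an S-adenosylmethionine synthetase, rose, by 2.24 ± 0.25 (SE), and it was also the 1 that rose adjusted over the list alone. MET6, methionine synthase, did not pass, at 1.02 ± 0.24 with an adjusted p of 0.0582. The call was lost without dis3-E729K replicate 2, where the median was 0.20 with an adjusted p of 0.0609. The median was 0.16 without wild type replicate 2, 0.40 without wild type replicate 1 and 0.40 without dis3-E729K replicate 1. MET17, the O-acetylhomoserine sulfhydrylase gene that BY4741 lacks, read 9.55 in wild type replicate 2 and 3.22 to 3.47, below background, on the other arrays.

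The other lists were not called by camera. In the DNA damage list, 2 of 25 genes rose, PHR1, the photolyase, by 2.02 ± 0.20 (SE) and MAG1, a DNA glycosylase, by 1.40 ± 0.21, and 8 fell, among them RAD53, a checkpoint kinase (-1.34 ± 0.17), PLM2 (-1.23 ± 0.13) and MSH6 (-0.91 ± 0.13). Adjusted over the list alone 3 rose and 11 fell. Its camera adjusted p was 0.185 (median -0.31), and its fry adjusted p, which asks whether the genes move one way on balance, was 0.0242. MSH6 and others of the 8 falls are also members of the G1/S list, so they are not separate from the falls there. In the respiration and tricarboxylic acid cycle list, NDI1, the internal NADH dehydrogenase, rose by 1.93 ± 0.22 and CIT1, citrate synthase, by 1.03 ± 0.18, and CYC1 fell by 0.58 ± 0.12; 41 of 44 genes did not pass, and 1 rose adjusted over the list alone (median 0.06, camera adjusted p = 0.185). Of 66 genes listed by name pattern as mitochondrial ribosomal protein genes, MRPL4, MRPL28, MRP20 and MRPL1 rose by 0.58 to 0.68, MRP8 rose by 1.34 and RSM27 changed by -0.72. A name match does not show that a member such as MRP8 encodes such a protein. In limma's test 0 passed adjusted over the list alone, with 14 higher and 8 lower at an unadjusted p under 0.05 (median 0.06, camera adjusted p = 0.254). In the iron list, MRS4, a mitochondrial iron carrier, rose by 2.07 ± 0.35 and ISU1, a scaffold for iron-sulfur clusters, by 1.36 ± 0.28, while ATX1, a copper chaperone, fell by 1.05 ± 0.12, as did FTR1, VHT1 and BIO5; adjusted over the list alone 3 rose and 4 fell. The camera adjusted p of the iron list was 0.972, and its mean and median lay below zero while the test's sign was positive. In the zinc list 4 of 15 fell, ZAP1, the zinc-responsive activator (-1.32 ± 0.22), MCD4, IZH1 and RAD27, as did 4 adjusted over the list alone (median -0.40, with -0.04 and -0.65 within the pairs, camera adjusted p = 0.254). RAD27 is also a member of the G1/S list. ZPS1, another gene of the zinc list, did not pass and read 13.41 in wild type replicate 2 and 10.91 to 11.22 on the other arrays. In the phosphate list PHM8 rose by 1.62 ± 0.28 and KCS1 and PHM6 fell; adjusted over the list alone 1 rose and 2 fell. PHM6 lay at background in the mutant, so its fold is not given (median -0.16, camera adjusted p = 0.478). In the list for the unfolded protein response of the endoplasmic reticulum EUG1, JEM1 and SCJ1 fell, with changes of -1.01, -1.45 and -0.78, and 4 fell adjusted over the list alone (median -0.40, camera adjusted p = 0.254). Of the genes named for these lists, PHR1, RAD53, PLM2, NDI1, MRS4, ZAP1, MCD4, PHM8 and JEM1 also passed with the replicate block, and the others did not.

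Of 49 genes for amino acid synthesis ARG4 rose by 0.68 and ARG2, LYS21 and SNZ1 fell, with 45 not passing (median -0.15, camera adjusted p = 0.185). In the ergosterol list ERG9 rose by 0.57 and ERG5 fell by 1.00 (median -0.25, camera adjusted p = 0.239). In limma's test 0 genes of either list passed adjusted over the list alone; at an unadjusted p under 0.05, 1 gene for amino acid synthesis was higher and 9 lower, and 2 ergosterol genes were higher and 7 lower. In the list for purine and pyrimidine synthesis only URA8 passed (median -0.06, camera adjusted p = 0.972), in the cell wall list only SWI4, which fell by 0.99 (median -0.11, camera adjusted p = 0.792), and among the COS genes only COS7, which rose by 0.75 on a probe set marked as cross-hybridising (median 0.21, camera adjusted p = 0.141). Adjusted over the list alone 1 rose, 1 fell and 2 rose in these lists, in that order. In limma's test 0 genes passed, over all genes or adjusted over the list alone, in 5 further lists. At an unadjusted p under 0.05, 2 of 17 genes of glycolysis and fermentation were higher (median 0.15, camera adjusted p = 0.0535) and 3 of 17 hexose transporters (median 0.23, camera adjusted p = 0.141). Of 10 histone genes 1 was lower at that level (median -0.13, camera adjusted p = 0.419), as were 3 of 13 seripauperin genes, most of whose probe sets are marked as cross-hybridising (median -0.35, camera adjusted p = 0.247), and 1 of 4 auxotrophic marker loci (median -0.52, camera adjusted p = 0.254). HXT4, a transporter induced when glucose is low, read 11.51 ± 0.72 and 13.01 ± 0.30 (SD, n = 2 each) and did not pass limma's test (adjusted p = 0.0703), but passed with the replicate block (adjusted p = 0.0470). HXT7, another such transporter on a cross-hybridising probe set, differed by 1.58 ± 0.49 (SE; adjusted p = 0.0893). With the block ARG4, ARG2, LYS21, SNZ1, ERG9, ERG5, SWI4 and COS7 did not pass.

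Replicates of both genotypes differed in mating type genes. MF(ALPHA)1, the alpha-factor precursor, read 4.95 in wild type replicate 1, 13.91 in wild type replicate 2, 4.72 in dis3-E729K replicate 1 and 13.66 in dis3-E729K replicate 2. STE3, the a-factor receptor that alpha cells make, read 7.88, 12.09, 7.01 and 11.81 in the same order, and STE2, the alpha-factor receptor of a cells, read 12.26, 7.01, 12.58 and 6.81. The 4 alpha-specific genes measured differed between replicates by a median of 5.73 in wild type and 4.81 in the mutant. Between genotypes they did not differ beyond that spread (median -0.56, -0.21 and -0.57 within the pairs, camera adjusted p = 0.972), with 0 of 4 passing limma's test and 0 at an unadjusted p under 0.05. BY4741 is a MATa strain. For the 7 a-specific genes, the median difference of replicate 2 from replicate 1 was -3.65 in wild type and -5.46 in the mutant. In the list for a mating type and pheromone response, PRM4 rose by 1.69 ± 0.28 (SE) and PRM3 and MSG5 fell, with changes of -0.77 and -0.65, as in the count adjusted over the list alone of 1 higher and 2 lower (median -0.16, camera adjusted p = 0.579). Of 46 genes for meiosis and sporulation, which these cultures should not express, 2 rose, IME4 by 0.94 and SPO11 by 1.09, and 8 fell, among them SPS4, SPO16, SPR1 and CRR1 with changes of -3.24, -1.43, -1.24 and -1.12 (median -0.13, camera adjusted p = 0.267). Adjusted over the list alone 4 rose and 10 fell. PRM4, SPS4, SPO16, SPR1 and CRR1 passed with the replicate block, and PRM3, MSG5, IME4 and SPO11 did not. SPR6, the brightest member, read 10.15 ± 0.14 and 9.98 ± 0.04 (n = 2) and did not pass.

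**Figure D3:**
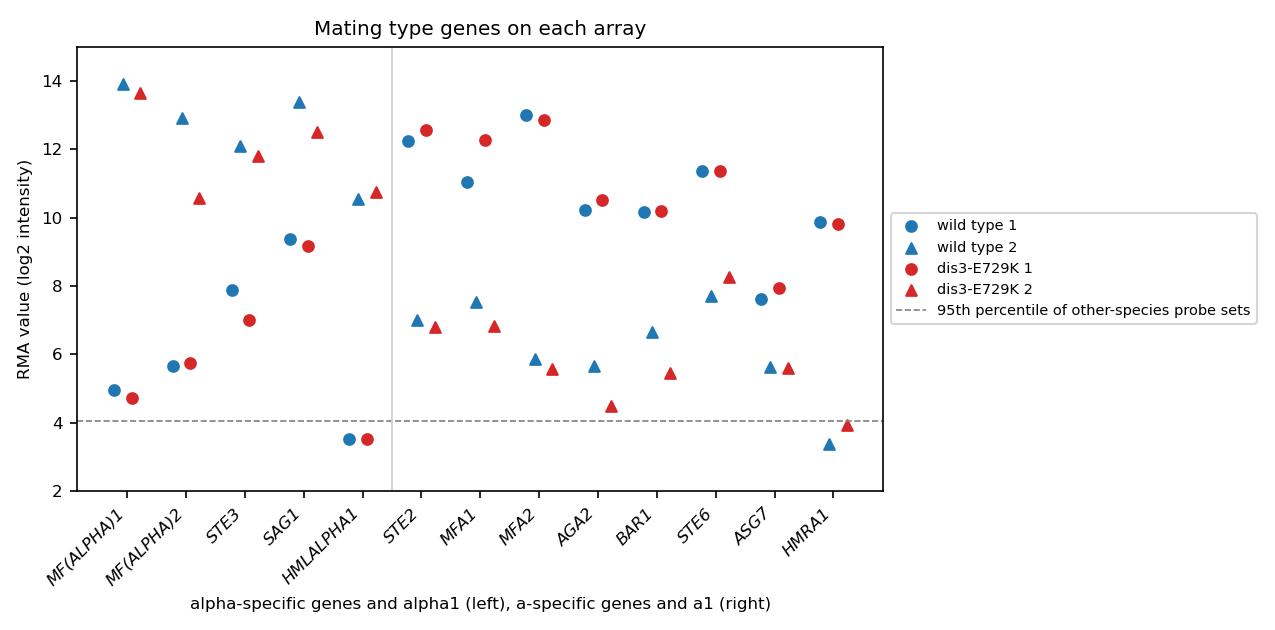
RMA values (log2 intensity, y axis) of mating type genes (x axis) on each of the 4 arrays, with a dashed line at 4.06, the 95th percentile of probe sets of the second yeast species. In both genotypes the alpha-specific genes are high in replicate 2 and the a-specific genes in replicate 1; MF(ALPHA)1 reads 13.91 and 13.66 in the replicate 2 cultures.

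As checks of the labels, DIS3 itself read 11.73 ± 0.12 in wild type and 11.30 ± 0.26 in the mutant (n = 2), a difference of -0.43 ± 0.18 (SE) that did not pass (adjusted p = 0.154). The allele differs by a missense change and is transcribed, so this level does not test the genotype. Of its protein-coding neighbours in assembly R64, TSR4, a factor of small subunit synthesis, fell by 1.10 ± 0.13 (adjusted p = 0.0336, and 0.0514 with the replicate block), and TAT2 did not pass (-0.11 ± 0.13, adjusted p = 0.549). URA3 was expressed in all 4 cultures, at 11.37 ± 0.01 and 11.05 ± 0.24 (n = 2; adjusted p = 0.211), and LEU2, deleted in BY4741, lay between 4.26 and 4.58. HIS3, which BY4741 lacks in part, read 11.43 ± 0.20 and 10.71 ± 0.31 (n = 2; adjusted p = 0.0850), so it gave signal in all 4 cultures. MET17, also deleted in BY4741, gave signal in wild type replicate 2, at 9.55; it lay below background on the other arrays, so no difference is given.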

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

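All tests of explanations in this part were chosen after the results were seen. With 2 arrays per group, no array was tested as an outlier, and the series has 1 contrast, so no other effect was set against it.

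Signal outside the genes tested came first from ribosomal RNA. Of 17 control probe sets for yeast ribosomal RNA 2 passed limma's test over all probe sets, higher in the mutant by 0.71 ± 0.12 and 0.73 ± 0.14 (SE; adjusted p = 0.0399 and 0.0447), and the median over the 17 was 0.4216, or 0.44 with arrays centred on the median. A rise in labelling or array brightness shared by all transcripts is argued against by the spiked Bacillus transcripts. Their median change was -0.1902, with 36 of 36 lower in both pairs. That fall is itself a difference between the groups, so another kind of difference in input or labelling stays open. More ribosomal RNA carried into the labelled material of the mutant preparations stays open. The smaller of the rises within the pairs was 0.3931, and between genotypes ribosomal RNA was higher while the spiked signal was lower. Within each genotype the array with more ribosomal RNA signal did not have less spiked signal. The medians of those ribosomal RNA differences were only 0.059 in wild type and 0.022 in the mutant, so this check decides little. A candidate biological explanation, retained or tailed ribosomal RNA in an exosome mutant, was not tested, and it cannot be told apart from carry-over here because the share of ribosomal RNA in the labelled material is not known.

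Of the other control probe sets 3 passed, all higher in the mutant: 2 for the 5' part of the control gene SRB4 and 1 for 18S ribosomal RNA of the second yeast species, by 0.75 to 0.77.

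Among 3470 probe sets with no gene here, 29 were higher and 11 lower in the mutant at an adjusted p under 0.05 in limma's test, with a median rise of 1.55 over the 29. Only 392 of the 3470 lay above background. The species that each was designed for is not given here, so they cannot be taken as S. cerevisiae transcripts. The largest of the 29 rises was from 6.97 to 10.08 (means, n = 2 each).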

How the results depend on the processing

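The alternatives were chosen before the data were examined. With the replicate block 199 genes were higher and 144 lower, of which 184 and 140 were among the 420 and 444; the block changed no list call. Same-numbered cultures are not said to share a day or batch, and their deviations correlated at 0.0839 across genes. That value reflects the bulk of genes and does not show the cultures to be unmatched, since mating type genes followed the replicate number in both genotypes. In the blocked fit 11 genes differed by replicate number at an adjusted p under 0.05 in limma's test, and 0 of them were called between genotypes. The main model, fixed beforehand, left the number out. With the block 46 of the genes recomputed by name no longer passed and 1 did so newly. Without variance moderation, with 2 residual degrees of freedom, 0 genes were higher and 2 lower (631 and 777 at an unadjusted p under 0.05). At an adjusted p of 0.1, 883 and 1069 passed. With each array left out in turn, the lone array assumed to vary like the other group, counts ranged from 0 to 316 higher and 0 to 351 lower; fewer arrays lower the power. The other settings kept both counts within 1.5 times. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 1 and 1; in other settings 4 to 6 lists were higher and 6 to 9 lower. Mean replicate agreement was r = 0.9635, and 0.9582 with dim genes left out. No variance moderation cost 109 of the genes recomputed by name their call, and leaving out dis3-E729K replicate 2 also 109; the cause was not tested.

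No gene that passed the test reversed among those recomputed by name; the other called genes were not checked one by one. Differences that did not pass and changed sign, as arrays were left out, ranged from -6.126 to 0.1991 for MET17, -4.722 to 4.243 for MF(ALPHA)1, -4.756 to 2.503 for MF(ALPHA)2, -2.537 to 1.475 for SAG1, -2.982 to 1.822 for STE3, -2.823 to 2.948 for STE2, -3.862 to 3.421 for MFA2, -3.531 to 3.7 for HMLALPHA1, -3.015 to 3.505 for HMRA1, -1.443 to 1.379 for HSP12, -1.851 to 2.317 for HXT5 and -2.349 to 0.1178 for ZPS1. Under quantile normalization STE2 moved to -0.01527 and HSP12 to 0.002945. MET17 lay below background on all arrays but wild type replicate 2, HMLALPHA1 in replicate 1 and HMRA1 in replicate 2 of both genotypes, so their values measure no exact change. Leaving out an array unbalances the split between single cultures that these genes follow. Only 57 genes lay under background, but LEU2, deleted in BY4741, read 4.26 to 4.58, above the level of 4.06. The level may therefore be low for S. cerevisiae probe sets, and the number of genes without true signal is not known.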

Other observations

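Tests in this part were chosen after the results were seen, except those of coding length and of dim transcripts; what counts against the latter's hypothesis was made stricter after its value was seen. A list of genes repressed by glucose was written after the data were seen and holds ADY2, SFC1 and JEN1, whose rise prompted it. Its count, 8 of 15 higher and 0 lower in limma's test, is therefore not independent evidence, and the list was not tested as a set. ICL1, isocitrate lyase of the glyoxylate cycle, rose 10.2-fold, from 8.47 ± 0.21 to 11.82 ± 0.54 (SD, n = 2), and MLS1, malate synthase, rose 5.24-fold. CAT8, an activator of these genes, did not pass, at 2.20 ± 0.67 (SE; adjusted p = 0.0879). Of 11 genes for peroxisomal beta-oxidation, a list also written afterwards, 3 rose and 1 fell.

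A further set of genes, among them HSP12 of the stress list, separated single cultures and not genotypes. HSP12 read 13.62 in wild type replicate 1, 11.70 in wild type replicate 2, 11.21 in dis3-E729K replicate 1 and 14.04 in dis3-E729K replicate 2, and HXT5 read 10.71, 6.55, 7.11 and 10.62. In wild type replicate 2 alone, MET17 (9.55), YOR387C (11.19 against 5.29 to 5.67) and ZPS1, a zinc-responsive gene (13.41 against 10.91 to 11.22), were high.

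Alpha-specific genes were high and a-specific genes low in replicate 2 of both genotypes. A minority of alpha cells in a cultures is argued against, since the a-specific genes differed by a median of -3.646 or lower, where a minority would lower them by at most 1. Loss of silencing, which would bring the a/alpha state, is argued against by haploid-specific genes, whose lower median difference was 0.1502. Replicate 2 cultures of the alpha mating type may account for the pattern. The a1 transcript, on the probe set annotated to HMRA1, lay below background in replicate 2. This bounds its difference from replicate 1 at -5.754 or lower with those readings set to the background. The alpha1 transcript, on the probe set annotated to HMLALPHA1, read 10.56 and 10.74 in replicate 2 and lay below background in replicate 1. The annotation does not show which locus the transcripts came from. Mating type was balanced between genotypes, but MET17 was not, at 9.55 in wild type replicate 2 and below background in dis3-E729K replicate 2. BY4741 is a MATa strain, so the alpha-type expression in replicate 2 of both genotypes goes against the labels. The labelled background also lacks MET17, so the signal in wild type replicate 2 goes against the label of that culture as well. The spread between the wild-type cultures therefore also holds their differences in mating type and MET17 expression. Whether the cultures differ at further loci stays open and untested.

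Stress genes were higher while growth genes were lower. Exhaustion of glucose predicts a fall of more than 1 in HXT1 and HXT3, transporters made when glucose is present. Their 95% intervals lay above -0.1169, so that fall was not seen. This does not decide on exhaustion, since the test rests on 2 genes picked after the results were seen. The list of genes repressed by glucose, also written afterwards, went with exhaustion, with 8 of 15 higher and 0 lower. Exhaustion and a partly lowered glucose level both stay open, with HXT2 at 1.73 ± 0.69 (SE, not passed). A trend with coding length is argued against as the whole cause, since 10 of 10 called lists kept their call after it was removed. The removal moved genes by a median of 0.059. It left 375 genes higher and 315 lower, against 420 and 444 in the main fit, so calls of single genes depended on the trend in part. Collection of the mutant at a later point of growth cannot be told apart from an effect of the allele, since density per culture is not given. Across genes, the genotype difference correlated at 0.53 with the difference within the mutant pair, and at 0.208 with wild type replicate 1 minus replicate 2. Each correlation has 2 arrays on both sides, so unequal deviation of single arrays can produce it, and it does not decide the cause. The difference within the mutant pair was then fitted to the genotype difference as an axis and subtracted, which lowers the spread of the genotype difference by construction. With that axis removed, 71 genes were higher and 55 lower, and 8 of 10 lists kept their call, with medians that moved from -0.76 to -0.36 for ribosome biogenesis, -0.22 to -0.10 for ribosomal proteins, 1.94 to 1.36 for stress genes, 0.42 to 0.35 for chaperones, 0.44 to 0.45 for the proteasome, -0.49 to -0.30 for G2/M genes, -0.40 to -0.305 for kinetochore genes and -1.01 to -1.03 for G1/S genes; the exosome list (-0.40 to -0.12, adjusted p = 0.206) and the sulfur list (0.25 to 0.24, adjusted p = 0.128) lost theirs, for reasons not tested. A later point of growth as the whole cause predicted at most 2 lists kept, which was not met, but the axis is a difference between single cultures and not measured growth, so this leaves it open.

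One hypothesis was that transcripts of low abundance rise more often in an exosome mutant. Among called genes, 44.4% of those with a mean under 9.28 and 50.7% of the rest were higher (128 higher and 160 lower against 292 and 284; Fisher's exact test, two-sided, p = 0.09672), so the predicted direction was not seen. By the criterion written beforehand, an equal or lower share counts against the hypothesis; by the later one, which also asks for a p under 0.05, the test leaves it open. A second, written once the counts had been seen, was that probe sets without a gene here rise more often than annotated ones. Of called probe sets, 72.5% of the unannotated and 49.0% of the annotated were higher (29 and 11 against 399 and 415; Fisher's exact test, two-sided, p = 0.005279). Only 392 of the 3470 unannotated probe sets lay above background, against 5435 of 5498 annotated ones, and a probe set at background can rise but not fall. Without called probe sets at background in either group, 28 unannotated ones were higher and 10 lower against 394 and 410 (Fisher's exact test, two-sided, p = 0.00418). Few called unannotated probe sets were left out, 1 at background in wild type and 1 in the mutant. LEU2, deleted in BY4741, read 4.26 to 4.58, above the level of 4.06, so a higher floor is possible. The test therefore does not decide on the floor. Because the counts of called probe sets prompted the hypothesis, the test on them does not support it, and it stays open. Probe sets are also not independent, and the transcripts and species of the unannotated ones are not given here. TSR4, beside DIS3, fell by less than 19 of the 89 ribosome biogenesis genes.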
